A study of Homo sapiens with 4 samples.

How the data were processed

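H3K9me3, the trimethylated form of lysine 9 of histone H3 that marks constitutive heterochromatin, was profiled by CUT&Tag in MCF7-ABER breast cancer cells. In CUT&Tag an antibody bound to chromatin in permeabilised cells directs a transposase that cuts and tags the DNA next to it, so sequenced fragments pile up where the mark lies. Per the labels' protocols, cells were grown in medium without phenol red and with charcoal-stripped serum, and libraries were made with a commercial CUT&Tag kit and an antibody against H3K9me3. The labels give 4 libraries, 2 from cells treated with a control antisense oligonucleotide (CtrASOM) and 2 from cells treated with an antisense oligonucleotide against SUV39H2 (SUVASO2M). Groups were taken from the treatment label of each library.

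The deposited data used here were 2 peak lists, 1 per treatment. Per the submitters' processing notes, fastp 0.23.1, Bowtie2 2.2.6, MACS2 2.2.7.1 and deepTools were used and positions refer to the build hg38; the notes as used here give no order or settings. Whether a list pools the 2 libraries of its treatment, and whether a control library was used, is not given in the sources used here. Per the file headers, each peak carries its position, a length, a fold enrichment, which is a ratio set by the authors' peak caller, a p-value with its FDR, and a score whose definition the headers do not give. The fold, p-value, FDR and score are the authors' own values for each peak. They were used here only to describe, rank or filter peaks within a list, apart from 1 ratio of score and fold given in the closing section. Each filter set the same bound in both lists, so a comparison of filtered lists also depends on how these values compare between lists. Every deposited peak had a fold of at least 2 and an FDR under 0.001 in the files. The depth of the libraries is not given in the files, and a deeper library gives more and longer peaks, so totals of the lists describe what was called, not an amount of H3K9me3.

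Because each treatment had 1 list, each was treated as 1 sample. No difference between lists has a replicate check, and no p-value was computed. A share of peaks is given with its 95% exact Clopper-Pearson interval, which covers counting error only. The ratio of covered length is given with a 95% bootstrap interval over 1 Mb windows (1000 resamples), which covers only the variation along the genome.

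Autosomes and X were used; 1 peak of the SUVASO2M list lay elsewhere and was left out. A peak counted as shared when at least 1 bp of it overlapped a peak of the other list, checked with bedtools 2.31.1. Chance overlap came from 100 random placements of the peaks, each within the stretch between the outermost peaks of its own chromosome, which ignores assembly gaps and copy number. Gene positions came from a table of RefSeq genes on GRCh38.p14, the same build, which held 19974 protein-coding genes on these chromosomes. This table gives the start and end of a gene without strand or exons. The planned promoter window (2 kb around the transcription start) was therefore replaced by 2 kb around either gene end, the planned gene body with 2 kb upstream by the gene body with 2 kb on both sides, and the split into exons and introns was not made.

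For each of 21 gene lists fixed before the data were examined, the difference in the share of each gene region covered by peaks (SUVASO2M minus CtrASOM, in percentage points) was computed. The median of a list was placed among 10000 random lists of the same size drawn from the same 10 classes of gene length, as a percentile from 0 to 100. A list was said to stand apart at or above 97.5 or at or below 2.5. Because most genes carried no peak, the median of 19 lists was 0, and the percentile of the list's mean was added after the data were seen. Lists were matched to the protein-coding genes of the gene table alone. These included 25 of 26 listed heterochromatin factors and 29 of 35 imprinted genes, and every gene of the other lists. Any listed imprinted gene that encodes a non-coding RNA was therefore not measured. The total covered length of a list counts overlapping gene regions once.

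Genes were named by a rule fixed before the data were examined. It took, per direction, the 12 genes with the largest difference in covered length whose direction was kept after the longer list was trimmed by score to the length of the shorter, the 8 genes with the highest authors' fold of a gene-end peak with no peak of the other list within 10 kb of that end, up to 4 members of each gene list, the 5 windows of 1 Mb with the largest difference, and SUV39H2, SUV39H1, CDK4, CDK6, CCND1, RB1 and ESR1 whatever their values. The requirement on trimming could exclude only genes covered more in SUVASO2M, since trimming removes SUVASO2M peaks alone. Of the members of a gene list, the 2 with the largest difference are given, and 4 for the ZNF genes on chromosome 19 and the neuronal list. This narrowing was made after the values were seen. The lists described at length were likewise picked from the 21 by their percentiles, so a high percentile in 1 list is to be read among 21 examined.

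Other settings fixed before the data were examined were a -log10 FDR above 5, an authors' fold of at least 4, the SUVASO2M list trimmed by score to the covered length of the CtrASOM list, other overlap rules, merging of peaks within 3 kb, gene-end windows of 1 kb and 5 kb, peak midpoints, windows of 5 Mb, gene ends in place of gene regions, and random lists matched on chromosome. Trimming by FDR, the mean of a list, matching on covered share, shifting a list along the gene order and the ZNF genes outside chromosome 19 as a list were added after the data were seen. Leaving out a library and a fit with replicate number as a block could not be run on lists without values per library.

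Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The interval code was tested on simulated data, with 0 mismatches in 10200 comparisons with counting base by base. When peaks were added to 200 of 19974 genes of the CtrASOM list, coverage was greater in 200 of them. Of 1000 random gene lists, 27 lay at or above the percentile 97.5 and 34 at or below 2.5. Together these were 6.1%, slightly over the 5% that the bounds imply. Their genes were drawn at random over the genome, so this share does not cover lists of neighbouring genes that share peaks. This last test was first run with fewer lists, gave a higher share outside, and was enlarged for that reason.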

Results

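H3K9me3 peaks were compared between MCF7-ABER breast cancer cells treated with an antisense oligonucleotide against SUV39H2 (SUVASO2M) or with a control oligonucleotide (CtrASOM). SUV39H2 is a histone methyltransferase that trimethylates lysine 9 of histone H3. The series concerns skipping of an SUV39H2 exon and resistance to CDK4/6 inhibitors, and the comparison asks where the mark differs once SUV39H2 is targeted. The labels give 2 libraries per treatment, and the values came from 1 peak list per treatment, so the differences below have no replicate check. The sequencing depth behind the lists is unknown.

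The target itself carried no H3K9me3 peak within 2 kb of its gene region (chromosome 10, 14878866 to 14904315) in either list. Peaks of this mark, present or absent there, do not measure whether the treatment acted on the target. SUV39H1, its paralog, and the cell cycle genes CDK4 and CCND1 also had no peak in either list. Peaks covered 4.26 kb of CDK6 in the CtrASOM list and 4.80 kb in the SUVASO2M list. ESR1, which encodes oestrogen receptor alpha, had 3.56 kb and 2.75 kb covered. RB1, the retinoblastoma tumour suppressor gene, had 1.89 kb and 1.56 kb covered. With peaks of -log10 FDR above 5 alone, the differences at CDK6 and RB1 turned to -0.672 kb and 1.56 kb, and with a fold of at least 4 those at RB1 and ESR1 turned to 0.233 kb and 0.018 kb.

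The SUVASO2M list held more peaks but these were slightly shorter. It had 71474 peaks against 66186 in the CtrASOM list, a ratio of 1.08. They covered 43.7 Mb against 41.8 Mb, a ratio of 1.05 with a bootstrap interval of 1.04 to 1.05. Median peak length was 482 bp in SUVASO2M and 502 bp in CtrASOM, and mean length 612 bp and 632 bp. By an overlap of at least 1 bp, most peaks of each list had a counterpart in the other, with lower shares under the stricter overlap rules given further below. Of the CtrASOM peaks 71.5% (71.1 to 71.8) overlapped a SUVASO2M peak, and of the SUVASO2M peaks 66.3% (65.9 to 66.6) overlapped a CtrASOM peak, where random placement gave 3.24% and 3.002%. Unshared peaks numbered 18886 in CtrASOM and 24099 in SUVASO2M, with a median length of 318 bp in both lists against 599 bp and 602 bp for shared peaks. The share overlapping went from 40.5% in the CtrASOM decile with the highest FDR to 97.8% in the decile with the lowest, and from 34.0% to 96.8% in SUVASO2M.

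**Figure D1:**
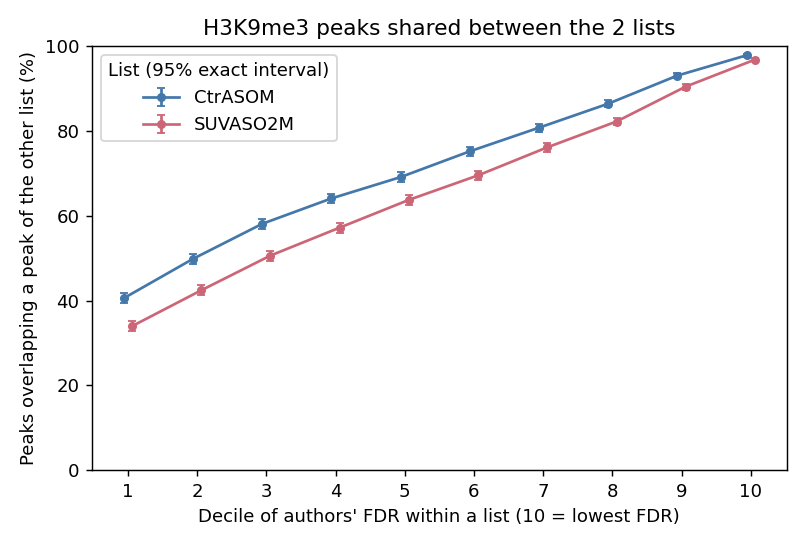
Percent of peaks of each list (vertical axis) that overlap a peak of the other list, by decile of the authors' FDR within the list (horizontal axis, 10 = lowest FDR). Points are shares and bars their 95% exact intervals; shares run from 40.5% to 97.8% in CtrASOM and from 34.0% to 96.8% in SUVASO2M.

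The ratio of covered length was highest on chromosomes 18, 16, 19, 21 and 20, while the largest difference in length was on chromosome 8, with 3.26 Mb in CtrASOM and 3.59 Mb in SUVASO2M. Covered length on chromosome 18 was 1.11 Mb in CtrASOM and 1.30 Mb in SUVASO2M, a ratio of 1.17, and the ratio was 1.16 on chromosome 16 and 1.13 on each of chromosomes 19, 20 and 21. Chromosomes 6, 1 and 14 had ratios of 0.964, 0.976 and 0.986, and the other 20 of 23 chromosomes had ratios above 1. With a fold of at least 4 the ratio was above 1 on all 23 chromosomes, 1.06 on chromosome 6 and 1.13 on chromosome 1 among them. The median fold was 3.96 in CtrASOM and 4.02 in SUVASO2M, so this bound lies near the middle of both lists. A small difference in fold over a whole list could therefore move this ratio on every chromosome, which was not tested. After trimming by score the ratio was above 1 on 10 chromosomes, with 0.826 on X and 1.13 on chromosome 18. Of 2862 windows of 1 Mb with peaks, 1616 (56.5%) were covered more in SUVASO2M and 1245 less. The share was 53.3% with -log10 FDR above 5 and 67.2% with a fold of at least 4, and 45.3% after the SUVASO2M list was trimmed by score to the length of the other, which balances the totals by construction.

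The window with the largest excess in SUVASO2M lay on chromosome 16 between 35 and 36 Mb, with no protein-coding gene, and went from 24.4 kb in CtrASOM to 45.8 kb in SUVASO2M. On chromosome 8 between 138 and 139 Mb, which holds FAM135B and the collagen gene COL22A1, coverage was 37.6 kb and 58.1 kb. The window of chromosome 19 between 31 and 32 Mb, which holds the zinc finger gene TSHZ3, had 13.3 kb and 33.1 kb. On chromosome 3 between 64 and 65 Mb, with ATXN7, PSMD6, PRICKLE2 and ADAMTS9, coverage was 98.98 kb and 118.1 kb, and on chromosome 7 between 153 and 154 Mb, with DPP6, 20.6 kb and 37.3 kb. The largest differences in the other direction were smaller. On chromosome 3 between 190 and 191 Mb, which holds the claudin genes CLDN1 and CLDN16 and IL1RAP, coverage was 24.8 kb in CtrASOM and 16.8 kb in SUVASO2M. A window of chromosome 12 between 97 and 98 Mb had 26.0 kb and 18.6 kb, one of chromosome 1 between 147 and 148 Mb with BCL9 and CHD1L had 34.2 kb and 26.8 kb, and one of chromosome 14 between 101 and 102 Mb with DIO3 and PPP2R5C had 33.3 kb and 26.0 kb. The window of chromosome 6 between 22 and 23 Mb with the prolactin gene PRL had 12.6 kb and 5.38 kb. Copy number, background signal and reads from repeated sequence were not tested for any of these windows. With peaks of at least 4-fold alone, the windows on chromosomes 8, 1 and 14 turned direction. The window of chromosome 3 with ADAMTS9 then had no peak in either list. The excess in the window of chromosome 16 was 9.66 kb with -log10 FDR above 5 and 3.64 kb with a fold of at least 4. The excess in the window with TSHZ3 was 2.77 kb with -log10 FDR above 5 and 0.283 kb with a fold of at least 4, and that in the window with DPP6 was 0.920 kb and 3.54 kb.

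**Figure D2:**
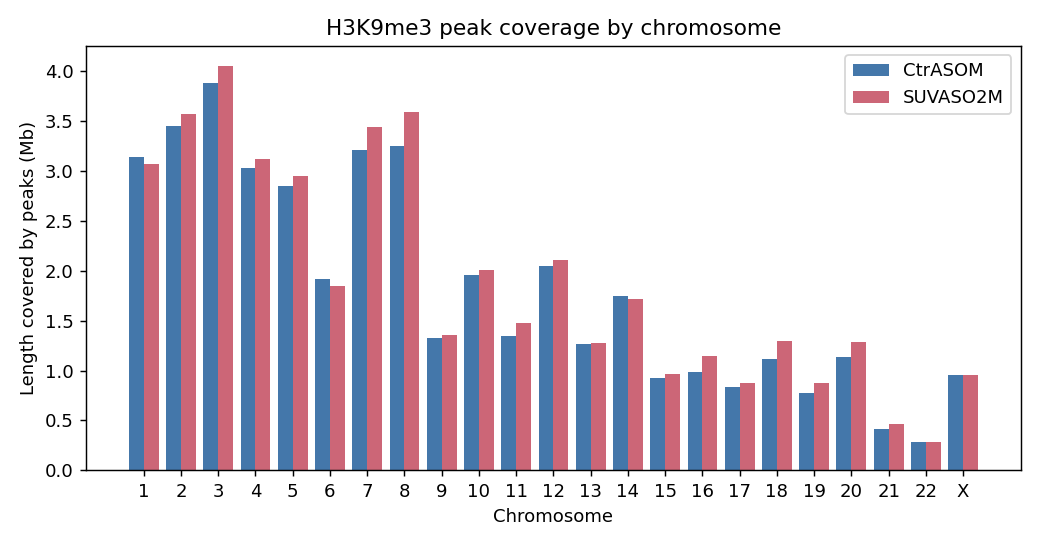
Length covered by H3K9me3 peaks (Mb, vertical axis) on each chromosome (horizontal axis) in the CtrASOM and SUVASO2M lists; each bar is 1 list, without replicates. SUVASO2M bars are higher on 20 of 23 chromosomes and lower on chromosomes 1, 6 and 14.

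Peaks lay mostly outside protein-coding genes, and nearly equally so in both treatments. Protein-coding genes held 32.7% of the peak-covered bases in CtrASOM and 32.8% in SUVASO2M, where random placement gave 43.0% for each. Regions within 2 kb of a protein-coding gene end held 3.41% and 3.50%, against 4.49% and 4.52% at random. Of 19974 protein-coding gene regions, 6258 carried peaks in both lists, 1196 in SUVASO2M alone and 884 in CtrASOM alone. Covered length was greater in SUVASO2M for 4458 genes and smaller for 3859, and after trimming by score it was greater for 3897 and smaller for 4138.

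A peak at a gene end was found in both lists for 2022 genes, in SUVASO2M alone for 982 and in CtrASOM alone for 693; after trimming by score these last counts were 772 and 770. Among ends occupied in SUVASO2M alone, the peak with the highest authors' fold lay at ZNF675 (chromosome 19, 23686730 to 23687120), a zinc finger gene, with a fold of 7.32. It was followed by the phosphate exporter gene XPR1 at 6.75, the transcription factor gene TCFL5 at 6.63, and a peak of 6.34 at the adjoining ends of CNST and TFB2M, a mitochondrial transcription factor gene. POLR1F, which encodes a subunit of RNA polymerase I, the calcium channel gene CACNA2D1 and CNOT4 had folds of 6.31, 6.31 and 6.30. Among ends occupied in CtrASOM alone, the highest fold was 6.21 at FBXL4 (chromosome 6, 98947516 to 98948212), a gene of mitochondrial maintenance. CCDC167, the kinesin gene KIF6 and the centromere gene CENPW, all on chromosome 6 as well, had folds of 5.68, 5.67 and 5.65. The corepressor gene TLE1 had 5.59, and a peak of 5.55 lay at the adjoining ends of the mitochondrial chaperonin genes HSPD1 and HSPE1, with HSPE1-MOB4 starting at the same place. These folds rank peaks within a list and do not measure a difference between lists. A peak at 1 end also need not match the whole gene region. XPR1, CNST, CNOT4 and CACNA2D1 were covered less in SUVASO2M over the region, and HSPD1 more.

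The genes with the largest excess of covered length in SUVASO2M were long, as ranking by length favours, and several act in neuronal adhesion. DPP6 (chromosome 7, 153748133 to 154894285), which encodes an auxiliary subunit of potassium channels, had 20.1 kb covered in CtrASOM and 34.0 kb in SUVASO2M, with 45 and 58 peaks. RALYL had 15.4 kb and 27.2 kb, the catenin gene CTNNA2 11.2 kb and 22.6 kb, CSMD1 23.6 kb and 34.8 kb, and the splicing factor gene RBFOX1 15.3 kb and 26.0 kb. The contactin-associated genes CNTNAP5 and CNTNAP2 had 6.50 kb and 33.4 kb in CtrASOM and 16.6 kb and 43.0 kb in SUVASO2M. The cadherin gene CDH4 had 17.9 kb and 27.2 kb, and CDH13 23.9 kb and 32.1 kb. The phosphodiesterase gene PDE1C had 25.6 kb and 35.7 kb, the phosphatase gene PTPRN2 33.3 kb and 42.2 kb, and the transcription factor gene ZFHX3 19.3 kb and 28.1 kb. All 12 kept their direction under both filters, but many differences were then small. With a fold of at least 4 the excess was 0.190 kb at PDE1C, 0.045 kb at ZFHX3, 0.996 kb at CDH13 and 1.11 kb at RBFOX1, and with -log10 FDR above 5 it was 0.868 kb at RBFOX1, against 5.02 kb and 8.15 kb at DPP6.

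Genes covered less in SUVASO2M differed by fewer bases. CNBD1 (chromosome 8, 86866415 to 87428652) had 45.5 kb covered in CtrASOM and 38.9 kb in SUVASO2M. The readthrough gene ZNF664-RFLNA had 9.85 kb and 4.62 kb, the cation channel gene TRPM2 10.8 kb and 5.92 kb, the lipoprotein receptor gene LRP1B 20.7 kb and 15.9 kb, and the syntrophin gene SNTB1 14.8 kb and 10.1 kb. CACNA2D1 had 15.3 kb and 10.7 kb although a peak at its end was called in SUVASO2M alone. CFAP299 had 17.3 kb and 13.3 kb, AFG2A 11.6 kb and 7.70 kb, the G protein subunit gene GNG7 5.72 kb and 1.97 kb, LYPLAL1 15.9 kb and 12.2 kb, SAMD5 6.00 kb and 2.30 kb, and MCC 7.12 kb and 3.45 kb. The direction turned for ZNF664-RFLNA, TRPM2, LRP1B, CFAP299 and GNG7 with -log10 FDR above 5, and for CNBD1, TRPM2, SNTB1, CFAP299 and LYPLAL1 with a fold of at least 4.

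ZNF genes on chromosome 19, which encode zinc finger proteins and lie in clusters rich in H3K9me3, were covered more in SUVASO2M. Of 246 genes, 138 were covered more, 63 less and 44 had no peak in either list. Their regions had 157.9 kb covered in CtrASOM and 196.9 kb in SUVASO2M, a ratio of 1.25, with 311 and 392 peaks. The median difference was 0.252 percentage points, at the percentile 100 among lists matched on gene length, and the mean of 0.569 points was also at 100. With -log10 FDR above 5, with a fold of at least 4 and with gene ends alone the median was 0 at the percentile 50.0, so the result by the median was not kept, while the mean was at 100 under both filters. ZNF69 had 2.15 kb and 4.86 kb covered, ZNF671 0.245 kb and 1.85 kb, and the long gene ZNF536 7.24 kb and 9.48 kb. ZNF274, whose protein brings H3K9 methylation to other zinc finger genes, had 3.83 kb in CtrASOM and 1.502 kb in SUVASO2M. ZNF536 and ZNF274 turned direction with -log10 FDR above 5, and these and ZNF69 with a fold of at least 4, and ZNF671 had no difference under either filter. After trimming by score the list had 195.0 kb in SUVASO2M, with 136 genes covered more and 63 less. Over all 509 ZNF genes, 221 were covered more, 129 less and 158 in neither list, with 415.4 kb in CtrASOM and 471.7 kb in SUVASO2M; the median was 0 at the percentile 50.0, and the mean was at 100. The members on chromosome 19 carried this mean, since the 263 ZNF genes elsewhere, with 83 covered more and 66 less, had a mean of 0.0396 points at the percentile 56.3. Outside chromosome 19, ZNF704 had 6.30 kb and 10.3 kb, with a difference of -1.45 kb at -log10 FDR above 5 and -1.0 kb at a fold of at least 4, and ZNF75D 5.33 kb and 1.81 kb. Reads shared between near-identical ZNF genes could make single members of the family uncertain, which was not tested.

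**Figure D3:**
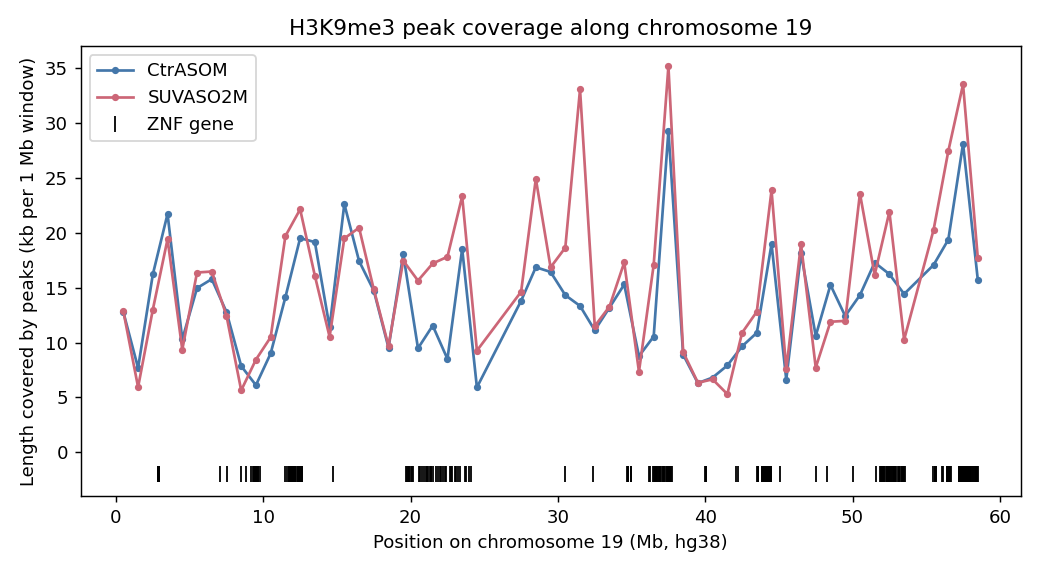
Length covered by H3K9me3 peaks (kb per 1 Mb window, vertical axis) along chromosome 19 (Mb in hg38, horizontal axis) in the CtrASOM and SUVASO2M lists; points are windows with peaks and ticks under the curves mark the 246 ZNF genes. The highest SUVASO2M excess is in the window from 31 to 32 Mb (13.3 kb and 33.1 kb), which holds no ZNF gene of the list. The 4 windows starting between 20 and 23 Mb are each higher in SUVASO2M (9.48 and 15.6 kb in the first). Some windows with ZNF genes are lower in SUVASO2M, among them that from 53000001 to 54000000 (14.4 and 10.3 kb).

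Of 30 neuronal adhesion and synapse genes, 20 were covered more in SUVASO2M, 8 less and 2 had no peak. Their regions had 427.3 kb covered in CtrASOM and 524.8 kb in SUVASO2M, a ratio of 1.23, led by DPP6, CTNNA2, CSMD1 and RBFOX1, whose values stand above. The median difference of 0.163 points was at the percentile 97.7 among lists matched on gene length. It was at 99.97 among lists matched on chromosome, which are not matched on length. As most genes carried no peak, a median above 0 can lie high among such lists whatever its size. The mean was at 99.3 among lists matched on gene length and at 99.6 after trimming by score. This position was not kept by the median with a fold of at least 4 (92.5), or by the mean among lists matched on covered share (76.8) or on chromosome (80.8). Nor was it kept by the mean with -log10 FDR above 5 (96.1), with a fold of at least 4 (76.4) or among shifts along the genome (84.8).

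With every peak used, genes of the pathways that the series concerns did not stand apart. Of 25 measured H3K9 methylation and heterochromatin factors, 6 were covered more and 6 less, with 20.8 kb in CtrASOM and 21.7 kb in SUVASO2M and a mean at the percentile 19.7. The methyltransferase genes EHMT1 and MECOM had 2.02 kb and 9.38 kb in CtrASOM and 3.93 kb and 7.65 kb in SUVASO2M, with MECOM turned at a fold of at least 4 and the difference at EHMT1 0.191 kb with -log10 FDR above 5. Of 31 genes of the G1-S transition and the CDK4/6 pathway, 5 were covered more, 4 less and 22 had no peak, with the mean at 44.9. FZR1 had 0.502 kb in CtrASOM and no peak in SUVASO2M. Of 25 genes of oestrogen receptor signalling, 5 were covered more and 3 less, with the mean at 70.6; CXCL12 had a peak of 0.778 kb in SUVASO2M alone. Of 26 growth factor and drug transport genes linked to drug resistance, 7 were covered more and 5 less, with the mean at 62.4. With -log10 FDR above 5, coverage was 11.1 kb in CtrASOM and 9.53 kb in SUVASO2M for the H3K9 factors, 4.97 kb and 4.46 kb for the G1-S genes with 2 covered more and 5 less, and 5.24 kb and 7.74 kb for oestrogen receptor signalling, whose mean was at 92.6. With a fold of at least 4 it was 10.8 kb and 13.7 kb, 5.90 kb and 7.02 kb, and 4.38 kb and 5.69 kb. Among the growth factor and drug transport genes, ERBB4 had 18.7 kb and 20.7 kb and IGF1R 2.11 kb and 1.51 kb, with IGF1R turned at -log10 FDR above 5.

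Among markers of other cell states, CDH2, which encodes N-cadherin, had 4.63 kb in CtrASOM and 12.3 kb in SUVASO2M, a difference that was 2.75 kb with -log10 FDR above 5 and 0.497 kb with a fold of at least 4. Of 24 basal, mesenchymal and stem cell markers, 4 were covered more and 8 less, with 19.004 kb in CtrASOM and 25.3 kb in SUVASO2M and the mean at the percentile 15.7. The balance turned to 4 more and 1 less with -log10 FDR above 5, where the mean was at 65.2, and to 5 more and 3 less with a fold of at least 4. With a fold of at least 4 the total turned too, to 8.38 kb in CtrASOM and 7.30 kb in SUVASO2M. PROM1 had 1.58 kb and 0.669 kb with a turned direction under both the FDR and the fold filter. Of 30 interferon and nucleic acid sensing genes, 8 were covered more and 5 less, with the mean at 48.9; IFI44 had 0.621 kb in SUVASO2M alone and OAS1 0.518 kb in CtrASOM alone. Of 29 imprinted genes, 7 were covered more and 9 less, with the mean at 69.7, and with -log10 FDR above 5 the balance turned to 8 more and 5 less. The overlapping imprinted genes ZIM2 and PEG3 on chromosome 19 each had 0.830 kb in CtrASOM, and 3.18 kb and 2.31 kb in SUVASO2M; the difference was 0.254 kb at both with -log10 FDR above 5, and none was left with a fold of at least 4.

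Clustered gene families differed in direction. Of 94 keratin-associated protein genes, 12 were covered more, 4 less and 78 had no peak, with 5.12 kb and 12 peaks in CtrASOM against 9.29 kb and 18 peaks in SUVASO2M and a mean at the percentile 99.9. KRTAP12-3 and KRTAP12-4 on chromosome 21 had 1.06 kb and 0.985 kb in SUVASO2M alone. With a fold of at least 4 the family's coverage was 2.09 kb and 1.54 kb. Its mean was at 89.8 with -log10 FDR above 5 and at 25.1 with a fold of at least 4, so it stood apart under neither filter, and KRTAP12-3 and KRTAP12-4 then had no difference. None of the 53 clustered protocadherin genes was covered more and 20 were covered less, but their regions overlap and held 9 peaks in CtrASOM and 5 in SUVASO2M, 6.55 kb and 5.77 kb, with the mean at 3.13. The protocadherin mean was at 0.660 among lists matched on covered share. PCDHGA7 had 3.06 kb and 1.33 kb and PCDHGA8 2.85 kb and 1.33 kb. With -log10 FDR above 5 the protocadherin coverage was 1.81 kb and 3.28 kb, with 2 genes covered more and 17 less and the mean at 14.7, and with a fold of at least 4 it was 0.849 kb in CtrASOM alone, with 20 genes covered less and the mean at 4.86.

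With every peak used, the remaining lists did not stand apart by median or mean among lists matched on gene length, although cancer-testis antigens were at 98.8 among lists matched on chromosome and ribosomal protein genes at 97.6 among lists matched on covered share. Of 392 olfactory receptor genes, 61 were covered more and 50 less (mean at 81.5), with OR1B1 at 2.53 kb and 0.669 kb (turned with -log10 FDR above 5) and OR2L13 at 6.204 kb and 4.49 kb (turned with a fold of at least 4). Of 28 taste and vomeronasal receptor genes, 2 were covered more and 2 less (mean at 62.0), with TAS2R16 at 0.199 kb and 0.764 kb and TAS2R1 at 6.71 kb and 7.13 kb (turned after trimming by score). Of 98 cancer-testis antigen genes, 12 were covered more and 4 less (mean at 86.1), but with 7.39 kb in CtrASOM and 6.96 kb in SUVASO2M, and the balance was 1 more and 1 less with -log10 FDR above 5. Under that filter the total turned to 0.669 kb in CtrASOM and 0.999 kb in SUVASO2M, and with a fold of at least 4 it was 2.33 kb and 2.08 kb. MAGEA4 had 2.44 kb in CtrASOM alone, with no difference under either filter, and MAGEC3 1.54 kb and 0.548 kb. Of 45 defensin genes, 1 was covered more and 3 less (mean at 20.3), or 1 more and 0 less under either filter, with DEFB121 at 0.770 kb in CtrASOM alone and DEFB124 at 1.27 kb and 0.532 kb (turned with -log10 FDR above 5). Of 78 UDP glucuronosyltransferase and cytochrome P450 genes, 21 were covered more and 26 less (mean at 50.6), a balance that turned to 24 more and 11 less with a fold of at least 4, with CYP24A1, the vitamin D hydroxylase gene, at 2.05 kb and 4.02 kb (no difference with a fold of at least 4) and UGT1A10 at 3.69 kb and 1.88 kb (turned with a fold of at least 4). Of 73 histone genes, 8 were covered more and 9 less (mean at 71.6), with H1-6 and H2AC6 at 0.922 kb and 0.357 kb in SUVASO2M alone. With -log10 FDR above 5, however, no histone gene was covered more and 10 were covered less, with 3.20 kb in CtrASOM and 1.48 kb in SUVASO2M and the mean at 0.0700, and H1-6 and H2AC6 had no peak in either list; with a fold of at least 4 the mean of the histone genes was at 18.1. The histone gene regions held only 6 peaks in CtrASOM and 9 in SUVASO2M without a filter, so single peaks count for several genes. The 10 histone genes covered less are therefore not separate changes, and the random lists do not match this sharing. Of 80 ribosomal protein genes, 10 were covered more and 3 less (mean at 85.7), with RPL31 at 0.580 kb and 1.43 kb and RPS14 at 0.370 kb and 0.938 kb. Of 39 HOX genes, HOXA3 alone had a peak, of 0.359 kb in SUVASO2M (mean at 45.1), and the 17 type I interferon genes had none in either list (mean at 43.3).

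**Figure D4:**
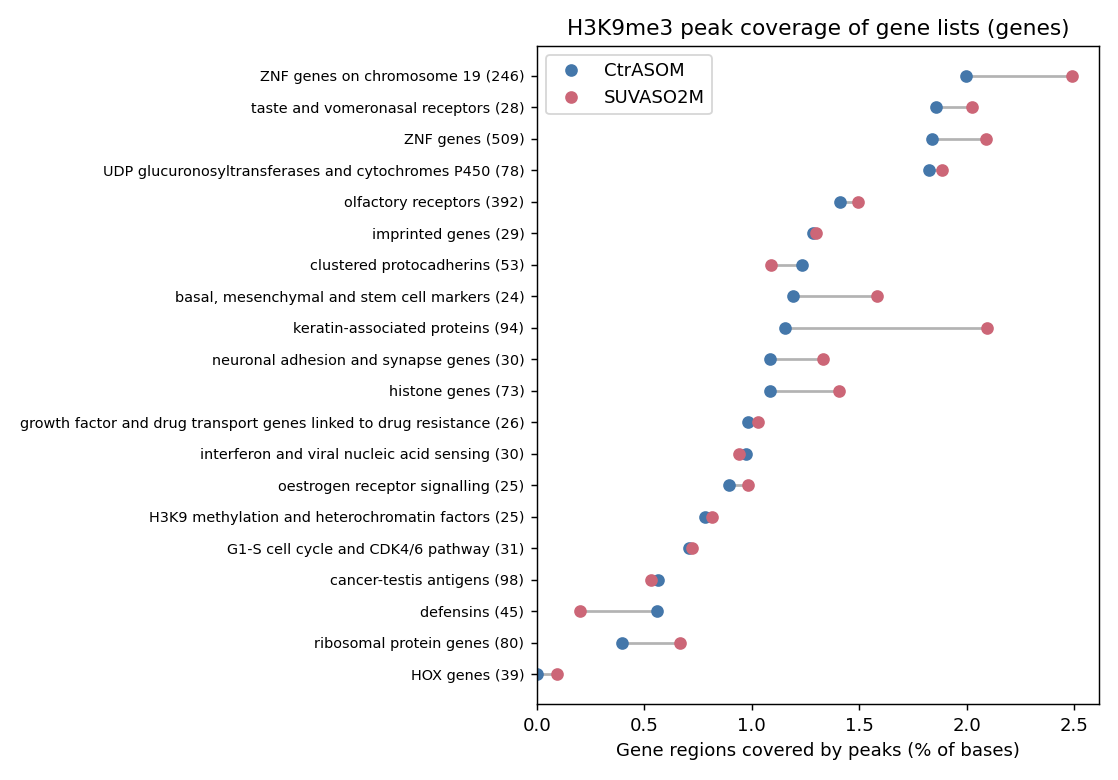
Percent of the bases of each list's gene regions that peaks cover (horizontal axis) in CtrASOM and SUVASO2M, with the number of genes in parentheses; lines join the values of a list, and a list with no peaks is left out. ZNF genes on chromosome 19 lie highest, at 2.00% and 2.49%, and keratin-associated protein genes lie farthest apart, at 1.15% and 2.09%.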

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

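Trimming by FDR, the mean of a list, matching on covered share, shifting along the gene order and ZNF genes outside chromosome 19 were chosen after the data were seen; the other alternatives were planned. No paired analysis was possible because each treatment had 1 list, without values per library; for the same reason leaving out a replicate gave no value. Trimming fixes the ratio of covered length at 1, so it gave no value for that ratio. The cause of the differences below was not tested. Of 296 comparisons of a named gene or window with 4 other settings, 24 could not turn, since those genes were chosen for a direction kept after trimming by score. Of the other 272, 209 had the same direction, 29 had no difference left and 34 turned. Of the 209, 72 differed in size by more than 1.5-fold. Trimming only removes SUVASO2M peaks, so a gene or window covered less in SUVASO2M could not turn under either trimming. Such comparisons beyond the 24 are among the 209, which therefore overstate how often a direction that could turn was kept.

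The ratio of peak number was 1.17 with a fold of at least 4, 1.01 after trimming by score and 1.01 after trimming by FDR; the ratio of covered length was 1.15 with a fold of at least 4 and 1.05 with peaks merged within 3 kb. The shared share of CtrASOM and SUVASO2M peaks was 65.0% and 59.9% with -log10 FDR above 5, 62.0% and 52.8% with a fold of at least 4, 69.3% and 68.8% after trimming by score, 69.4% and 68.6% after trimming by FDR, 61.1% and 56.6% with 50% of the peak overlapping, 53.4% and 49.5% with reciprocal 50%, and 72.8% and 67.5% with merged peaks. Windows covered more in SUVASO2M were 53.3% with -log10 FDR above 5, 67.2% with a fold of at least 4 and 59.5% with windows of 5 Mb, but 45.3% and 47.2% after trimming by score and by FDR, which balances the totals by construction. Genes with an end peak in both lists, in SUVASO2M alone and in CtrASOM alone were 824, 551 and 398 with -log10 FDR above 5; those in both lists were 950 with a fold of at least 4 and 3657 with 5 kb around gene ends. The share of covered bases near a gene end in CtrASOM and SUVASO2M was 2.13% and 2.25% with 1 kb, and by peak midpoints 3.65% and 3.82%.

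The percentile of the ZNF genes on chromosome 19 was 50.0 with -log10 FDR above 5, with a fold of at least 4 and with gene ends alone, where most genes had no difference and the median was 0; its mean was at 100 under both filters. The percentile of the neuronal list was 92.5 with a fold of at least 4, 96.2 after trimming by FDR and 50.0 with gene ends alone. The percentile of its mean was 96.1 with -log10 FDR above 5, 76.4 with a fold of at least 4, 80.8 when matched on chromosome, 76.8 when matched on covered share and 84.8 when shifted along the genome.

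With -log10 FDR above 5, the difference turned to 0.926 kb at ZNF664-RFLNA, 2.05 kb at TRPM2, 0.734 kb at LRP1B, 0.731 kb at CFAP299, 0.266 kb at GNG7, 0.529 kb at IGF1R, 0.669 kb at PROM1, 0.341 kb at OR1B1, 0.532 kb at DEFB124, 0.583 kb at ZNF274, 1.56 kb at RB1, -0.672 kb at CDK6, -1.45 kb at ZNF704 and -0.334 kb at ZNF536. With a fold of at least 4, it turned to 6.78 kb at CNBD1, 0.020 kb at TRPM2, 0.187 kb at SNTB1, 0.404 kb at CFAP299, 2.90 kb at LYPLAL1, 2.65 kb at MECOM, 0.018 kb at ESR1, 0.145 kb at PROM1, 0.661 kb at OR2L13, 0.181 kb at UGT1A10, 0.450 kb at ZNF274, 0.233 kb at RB1, -1.0 kb at ZNF704, -0.511 kb at ZNF69 and -1.73 kb at ZNF536, and to -1.63 kb, 0.102 kb and 0.887 kb in the windows of chromosomes 8, 1 and 14. Trimming by score turned TAS2R1 to -0.137 kb, and trimming by FDR turned ZNF536 to -0.217 kb. No difference was left under either the FDR or the fold filter at CXCL12, IFI44, OAS1, TAS2R16, KRTAP12-3, KRTAP12-4, MAGEA4, DEFB121, H1-6 and ZNF671.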

Other observations

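Regions of protein-coding genes had 14387.5 kb covered in CtrASOM and 15098.0 kb in SUVASO2M, a ratio of 1.05. Regions of 1196 snoRNA genes had 33.7 kb and 45.7 kb covered (ratio 1.36), with peaks at 67 and 97 of the genes, those of 1911 miRNA genes 57.6 kb and 75.4 kb (1.31) and those of 443 tRNA genes 11.1 kb and 13.7 kb (1.23). The largest snoRNA difference was in the imprinted snoRNA cluster on chromosome 15 between 25 and 26 Mb. There the regions of 80 genes from SNORD109A to SNORD109B had 1.36 kb in CtrASOM and 4.32 kb in SUVASO2M, with peaks at 4 and 14 of the genes. These regions overlap, so 1 peak can count for several genes, and reads shared between similar copies were not tested. Among tRNA genes, the cluster of 19 cysteine tRNA genes on chromosome 7 between 149 and 150 Mb had 1.57 kb and 2.21 kb, while the cluster of 56 tRNA genes on chromosome 6 between 27 and 28 Mb had 1.25 kb and 0.832 kb. Regions of 15212 pseudogenes had 1268.6 kb and 1399.3 kb (1.10), and those of 18177 lncRNA genes 8157.7 kb and 8587.4 kb (1.05). These groups were looked at after the data were seen, their differences were not placed among random lists, and the groups were not tested against each other. Their coverage was not computed under the FDR or the fold filter.

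Outside the fixed lists, the gene families with the highest coverage in CtrASOM, among families of at least 10 genes, were the aldo-keto reductases AKR (3.37% of bases), the zinc finger genes named ZFP (3.03%), the WFDC protease inhibitors (2.95%) and the cystatins CST (2.90%). In SUVASO2M these had 3.42%, 3.11%, 3.20% and 3.07%. The peak numbers in the files were not continuous, with 242 absent up to 66428 in CtrASOM and 230 absent up to 71705 in SUVASO2M. Of these, 97 and 96 lay between peaks of chromosome 20, and 58 and 54 between peaks of chromosome 17. Chromosome 3 had 26 and 23, chromosome 1 had 25 and 20, and chromosome 15 had 18 and 20. Peaks beside absent numbers had a median fold of 2.73 and 2.72, against 3.96 and 4.02 in the whole lists. The absent peaks were not analysed here.

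The tests by the list mean, by matching on covered share, by shifts along the gene order, by shuffles over the genome and within chromosomes and by the ratio of score and fold were chosen after the data were seen, as were the patterns; the ZNF list was fixed beforehand and picked here for its percentile. The first pattern is the greater coverage of ZNF genes on chromosome 19 in SUVASO2M. At the percentile 99.99 among lists from chromosome 19, the mean difference argues against an equal shift of all genes of that chromosome. At 99.89 among lists matched on covered share over the genome, it argues against a larger change wherever more of a gene is covered. No lists were matched on both, so a rise in proportion to coverage on chromosome 19 alone was not tested and stays open. With -log10 FDR above 5 the mean was at 100, so the excess was not confined to peaks close to the authors' threshold. This filter sets a new threshold with peaks close to it, so an effect of thresholds stays open. Among 1450 shifts along the gene order of chromosome 19, the mean was at 99.7. ZNF genes are each other's neighbours in clusters, so a rise of whole clusters as blocks would also give a high percentile. Shifts by a few genes also overlap and are not separate trials. Neighbouring genes that move together therefore stay open. The highest shift mean was 0.651 points, above the 0.569 points of the list. Reads shared between paralogs and a difference between the libraries behind the lists were not tested and stay open. That the oligonucleotide treatment goes with more called H3K9me3 at these genes is a hypothesis found and tested on the same lists. With 1 list per treatment it cannot be decided here.

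The second pattern is that peaks of 1 list without a counterpart gathered in the same 1 Mb windows. The net unshared length had an SD of 2.30 kb over 2846 windows. The highest of 1000 shuffles of the list labels was 1.98 kb. The shuffles move the label of each peak on its own, so they argue only against peaks that scatter independently of their neighbours. Neighbouring peaks that are called or lost together would exceed the shuffles too, whatever the reason, and this stays open. Chromosomes held 7.67% of the variance of the net length, above the 2.68% that was the highest of the shuffles. The bound of 50% set for copy number of whole chromosomes decides nothing, since 32.4% of the variance lay beyond the scatter of single peaks. Shuffles within each chromosome reached at most 2.08 kb. They also move single labels, so they do not decide whether whole chromosomes are the only cause, and a part of unknown size stays open. Copy number of smaller segments and the treatment itself were not tested and stay open.

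The third pattern is the greater covered length in SUVASO2M. The ratio was 1.04 (1.03 to 1.05) with -log10 FDR above 5, so the excess was not confined to peaks close to the authors' threshold. Peaks close to the new threshold remain under this filter, so an effect of thresholds stays open. More reads behind the SUVASO2M list cannot be told apart from the treatment, because depth is not given in the sources used here. The lowest value of (score + 1)/fold in SUVASO2M was 0.972 times that in CtrASOM, and what this says of depth is open while the score has no stated definition. This test was first read as arguing against depth and was set to undecided afterwards for that reason.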
